A study of Escherichia coli with 24 samples.

How the data were processed

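DNA depth along the Escherichia coli chromosome was compared in 24 libraries from 4 strains, each prepared by 3 methods in 2 biological repeats. Cells were grown at 37 °C in LB with 0.2% arabinose to an OD600 of 0.2 to 0.25, per the labels. The phenol-chloroform libraries came from enzyme-treated cells, organic extraction and the Nextera XT kit. The libraries called IN in the labels, named fixed here, were treated with 1% formaldehyde for 10 min at 22.5 °C, quenched with 0.5 M glycine and sonicated. The sonicated libraries had the same sonication (30 s intervals, 10 min, 5 °C) without the fixing. DNA of both sonicated methods was purified on MinElute columns and made into libraries with the NEBNext ChIP-Seq kit.

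The deposited tables give the signal as whole-number depth of coverage at each base of a sequence of 4630783 bases, in 1 column per library and not scaled between libraries. The submitters' processing notes name BWA and SAMtools, with no version, read length or genome build. Empty cells and cells marked NA were read as a depth of 0. Column headings hold the strain and a letter, A or B. The letters were taken as the 2 biological repeats of that strain and method, but they were not matched to the repeat numbers of the labels. The study's design text says that 4 samples came from an earlier series, without naming them by strain or method.

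Mean depth was 267 ± 72.0 (SD, n = 24) and ranged from 146 to 441, and on average 99.99% of bases were covered. Depth was averaged in 1 kb bins (4631 bins, the last of 783 bases) and divided by the library's mean over bins. Values were taken to log2 after adding 0.01. Bins with a mean relative depth under 0.25 would have been left out, and there were 0 of these. Because reads cover many bases each, depth is no count of independent molecules, and errors rest on the libraries.

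No genome sequence of the files' build was at hand, and the gene table at hand belongs to another build, so no gene coordinate was used. In place of the gene positions in the plan, landmarks were found from the depth tables. The ruvAB deletion was the longest stretch absent in every deletion library and present in every ruvAB+ library. The break site was the stretch of near-0 depth in all 12 libraries with the palindrome and in none of the other 12. Origin and terminus were the corners of a tent-shaped fit to the mean profile. The site opposite the break, as far from the origin on the other arm, served as a control and is called the mirror site.

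Indices were computed per library as differences of mean log2 relative depth. The lacZ index is the mean within 100 kb of the break on both sides, without the nearest 5 kb, minus the mean of flanks at 300 to 600 kb on both sides. The lacZ side difference is the origin-side window minus the terminus-side window. The log2 ori:ter ratio compares the 50 kb on each side of the origin and of the terminus. The terminus index is the 50 kb around the terminus minus flanks at 150 to 300 kb. Between-bin noise is the SD of log2 depth after a running median of 51 bins was taken off.

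Differences of indices were tested by exact two-sided permutation of the strain labels within each method. With 12 libraries the smallest p such a test can give is 0.00926. The difference of 2 such effects was tested by exact permutation within method and genotype, and the spread over methods by exact permutation of method labels within strain, taking the range as the statistic. Tests over all 24 libraries drew 100000 permutations. Bins were tested with limma (lmFit and eBayes with trend) in 1 fit of the 12 group means, with Benjamini-Hochberg adjusted p under 0.05 over the bins of each contrast. Runs of at least 5 neighbouring called 10 kb bins are given as regions. The bin model and the index test were tested on simulated data for the break effect in the deletion, averaged over methods, while the tests of genotype difference, of method spread and of noise were not. Among 100 simulated bins shifted by 0.3 all were recovered, at 0.1 62.0% were, and 4.14% of calls were false. The simulated errors were independent between bins, which those of real bins of the same library need not be. The 4.14% is thus not a false-call rate of the real counts. The lacZ index test passed its threshold in 97.0% of 200 simulations at a shift of 0.1, in 47.5% at 0.05 and in 5% at 0. The simulated shift and SD were equal in all methods, so these shares do not hold for an effect or spread that differs between methods.

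The indices, tests, windows and a first set of other settings were fixed before the data were examined. These settings were other window widths, the median over bins, 5 kb and 10 kb bins, other scalings, a pseudocount of 0.1, no filter, removal of the replication gradient, library weights, a fit per method, and leaving out each library. Added after the data were seen were the contrasts and regions within 1 method, the tests of each window alone, and the tests of strain segments, steps and peaks. Also added were settings that leave out the phenol-chloroform ruvAB+ libraries without the break, count the phenol-chloroform deletion pair without the break as 1 library, leave out strain segments, remove the method baseline, or rescale the values by distance, and the settings for the share of bins near the break that were lower with phenol-chloroform. Not run for want of a matching genome were the gene table, the named genes, the prophage lists and the GC correction. Strain segments, short stretches whose group mean depth differed by strain in the same direction in every method, were left out of the values by distance and of the search for steps. A step is the jump at a position when a line with 1 slope and a jump there is fitted to the log2 break effect in the 60 kb on both sides.

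Computation used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.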

Results

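Marker frequency analysis reads the copy number of each part of a chromosome from sequencing depth. Here it was applied to 4 Escherichia coli strains that differ in a chromosomal double-strand break and in ruvAB, the genes of the complex that moves Holliday junctions in recombinational repair. Strains DL4184 and DL4243 carry a palindrome in lacZ (lacZ::pal246). The palindrome is cut by the SbcCD nuclease, whose genes are under the arabinose promoter in all 4 strains. Strains DL4201 and DL4257 lack the palindrome. DL4243 and DL4257 also lack ruvAB. Each strain was prepared by phenol-chloroform extraction, by formaldehyde fixing with sonication (fixed), and by sonication alone (sonicated), with 2 biological repeats in each of the 12 groups. Mean depth per base was 249 ± 60.8 (SD, n = 8) in phenol-chloroform, 247 ± 95.6 (SD, n = 8) in fixed and 305 ± 41.2 (SD, n = 8) in sonicated libraries. Positions are those of the deposited tables, whose genome build was not stated.

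Both engineered loci were visible in the depth itself. The ruvAB deletion appeared as a gap of 1592 bases from 2652923 to 2654514. Depth over it was 59.3% ± 4.03 of the library mean in ruvAB+ libraries (SD, n = 12). In the deletion strains it was at most 0.0219% in the 4 phenol-chloroform libraries, and 0.259% to 0.531% in the 8 fixed and sonicated ones. At the break site, 14 bases from 1075014 to 1075027 had a depth of 0 or 1 in all 12 libraries with the palindrome. The same bases had 74.5% ± 14.6 of mean depth in the 12 libraries without it (SD). The origin estimate lay at 1.5 kb, the terminus estimate at 2309 kb, and the distance from break to ruvAB was 1579 kb.

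The deposited design compares the profiles obtained by the 3 methods. The fall in depth from origin to terminus was largest in sonicated DNA. The mean log2 ori:ter ratio was 1.83 in sonicated, 1.64 in fixed and 1.61 in phenol-chloroform libraries, each over 8 libraries. This range of 0.22 exceeded that of permuted method labels (p = 1.2e-04, permutation test). Local unevenness between neighbouring bins also differed. Its SD was 0.31 ± 0.017 in sonicated, 0.27 ± 0.035 in phenol-chloroform and 0.18 ± 0.013 in fixed libraries (SD over 8 libraries each). The range of 0.13 had p = 1e-05, the smallest that 100000 permutations can give. At the scale of 1 kb, limma called 89.3% of bins between phenol-chloroform and sonicated, 82.4% between fixed and sonicated, and 81.2% between phenol-chloroform and fixed libraries.

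In cells without RuvAB, how far depth around lacZ was lower with the break differed between the preparation methods in these libraries. In phenol-chloroform libraries of the ruvAB deletion, a deep and wide valley lay over the break site. At 5 to 25 kb from the break, depth with the break was 0.70 times that without it on the origin side (log2 -0.52 ± 0.13, SE, 2 libraries against 2). On the terminus side it was 0.65 times that without it (-0.62 ± 0.12). The valley reached farther towards the terminus, where depth at 200 to 400 kb was still 0.904 times that without the break (-0.15 ± 0.024), than towards the origin (0.014 ± 0.018 at that distance). In fixed and sonicated libraries of the same strains, depth at 25 to 50 kb on the origin side of the break was higher by 8.93% (0.12 ± 0.011) and 5.57% (0.078 ± 0.0098) relative to the library mean, but 0.0093 and -0.076 on the log2 scale when scaled to the terminus window. On the terminus side, the log2 difference with sonication was -0.092 ± 0.016 at 5 to 25 kb and -0.057 ± 0.014 at 50 to 100 kb, and in fixed libraries it was -0.012 ± 0.0097 and -0.013 ± 0.0061. Scaled to the terminus window these were -0.25 and -0.21 with sonication and -0.13 and -0.13 in fixed libraries, beside -0.66 and -0.44 with phenol-chloroform.

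In phenol-chloroform libraries of the deletion, limma called 426 bins (9.20%), of which 398 were lower with the break. Scaled to the library median, 14.3% were higher and 7.36% lower, and in 10 kb bins 17.5% and 16.2%. Of the 200 bins within 100 kb of the break, 176 were lower, and 397 of the 398 lay within 600 kb of it. The lowest bin, at 1078.5 kb, fell by 0.83 on the log2 scale, and its depth thus fell by 43.9%. In 10 kb bins the lower region ran from 940 to 1630 kb. Both phenol-chloroform libraries with the break showed the valley, at different depths: their lacZ indices were -0.28 and -0.45, against -0.0090 and -0.014 in the pair without it. Without library B, the deeper of the pair, 5.31% of bins were called. The corresponding phenol-chloroform libraries of the ruvAB+ strain with the break had lacZ indices of -0.052 and -0.054. Compared directly, the break strains with and without ruvAB differed in 438 bins (9.46%, limma).

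**Figure D1:**
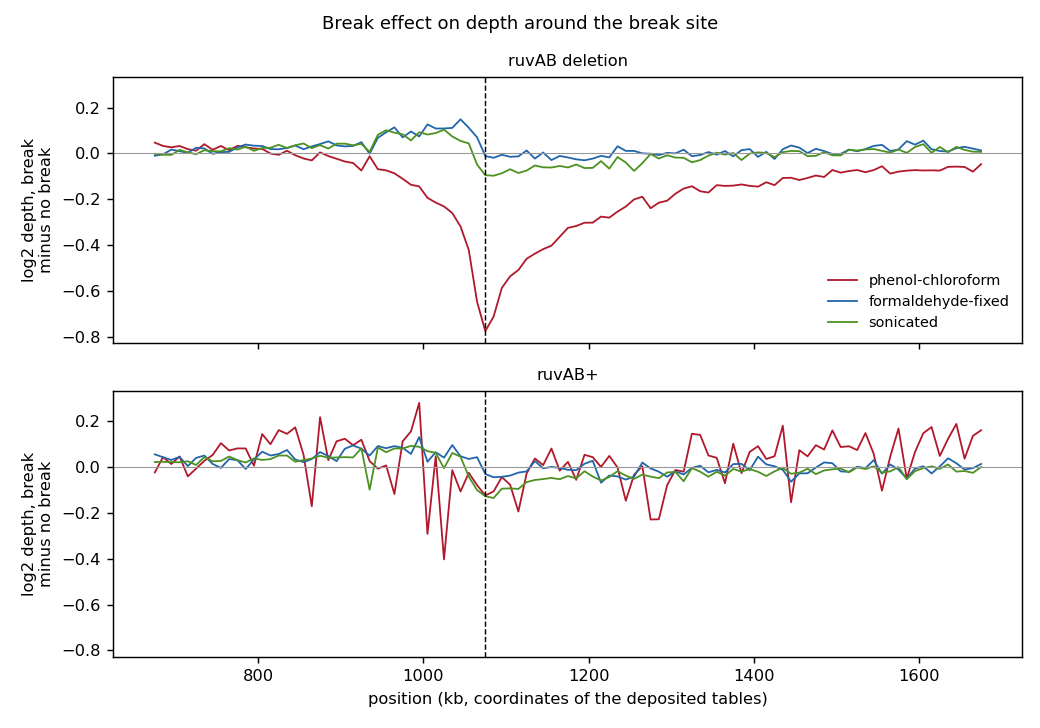
Log2 depth with the break minus log2 depth without it, in medians of 10 kb, from 400 kb before to 600 kb after the break site (dashed line), for the ruvAB deletion (top) and ruvAB+ (bottom). Lines are means of 2 libraries against 2 for each method. Only the phenol-chloroform line of the deletion forms a deep valley, and the phenol-chloroform line of ruvAB+ includes a pair without the break whose local profile differed from the other phenol-chloroform libraries.

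The bin model called this difference between methods near the break, while the planned index test did not pass. That model assumes 1 spread per bin for all 12 groups. The SD of the lacZ index was 0.12 in phenol-chloroform deletion libraries with the break (n = 2). It was 0.0027 to 0.0053 in the fixed and sonicated deletion groups. The model may thus understate the phenol-chloroform spread there, and its calls on neighbouring bins are no independent support. The break effect in the deletion was lower with phenol-chloroform than with sonication in 278 bins and higher in 6 (6.13% called). Against fixed libraries it was lower in 316 bins and higher in 16 (7.17% called). Of the bins within 100 kb of the break, 88.5% were lower than with both other methods, and 35.5% when depth was scaled to the terminus window. Over these bins the mean log2 difference was -0.39 ± 0.093 against sonicated and -0.44 ± 0.093 against fixed libraries, and -0.27 ± 0.11 and -0.36 ± 0.097 with that scaling (SE, 2 libraries per group). Fixed and sonicated libraries differed in 0 bins (limma), and in 49 at an unadjusted p under 0.05. The 49 are fewer than that threshold gives by chance, so the 0 does not show that these methods had equal break effects. At 5 to 25 kb on the terminus side the effect was -0.012 ± 0.0097 in fixed and -0.092 ± 0.016 in sonicated libraries. On the origin side it was 0.097 ± 0.027 and 0.023 ± 0.011 (SE, 2 libraries per group). The lacZ index averaged over methods changed by -0.11 in the deletion (exact permutation p = 0.287), from -0.35 ± 0.086 with phenol-chloroform, 0.033 ± 0.0042 in fixed and -0.0052 ± 0.0034 in sonicated libraries (SE, 2 against 2). The sonicated value was -0.025 with narrower windows and -0.040 with medians over bins, and the fixed one 0.023 with medians. The spread of 0.39 over methods did not pass its planned exact permutation test (p = 0.187). It passed once the method baseline had been removed, a test chosen after the data were seen (p = 0.0356, exact permutation). When depth was scaled to the terminus window, fewer bins differed between phenol-chloroform and sonicated libraries (1.58%) and between phenol-chloroform and fixed libraries (3.09%). Without phenol-chloroform library B of the deletion with the break these shares were 3.63% and 4.47%.

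The break also left the origin side of lacZ better covered than the terminus side, in every method in the ruvAB deletion. The side difference rose by 0.14 (a ratio of 1.10), from 0.19 ± 0.013 with phenol-chloroform, 0.10 ± 0.00073 in fixed and 0.13 ± 0.015 in sonicated libraries (SE, 2 against 2). This had p = 0.00926, the smallest that the exact permutation test can give. In ruvAB+ the side difference was 0.10 ± 0.011 higher with the break in sonicated and 0.064 ± 0.0037 higher in fixed libraries, and -0.025 ± 0.045 with phenol-chloroform. Their mean of 0.047 did not pass (exact permutation p = 0.111). It passed with narrower windows (0.041, p = 0.037), wider windows (0.074, p = 0.00926), with the strain segments left out (0.058, p = 0.037), and without phenol-chloroform library B of ruvAB+ without the break (0.062, p = 0.00926), all by exact permutation. The difference between the genotypes, 0.093, was not past the threshold (exact permutation p = 0.0945).

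Measured against the flanks at 300 to 600 kb, the terminus-side window was lower with the break in both genotypes. Its mean over methods was -0.18 in the deletion, ranging from -0.45 with phenol-chloroform to -0.019 in fixed libraries, and -0.051 in ruvAB+. Each had the smallest exact permutation p, 0.00926, in a test chosen after the data were seen, and the 2 genotypes' effects were not shown to differ (exact permutation p = 0.272). Without the phenol-chloroform ruvAB+ pair without the break, the ruvAB+ value, then a mean of fixed and sonicated libraries only, was -0.049. It had p = 0.0556, the smallest the exact permutation test can then give. The origin-side window changed by -0.038 in the deletion (exact permutation p = 0.500), with -0.26 for phenol-chloroform, 0.085 for fixed and 0.058 for sonicated libraries. At the mirror site on the other arm, the index changed by -0.0039 with the break in the deletion (exact permutation p = 0.287) and by -0.036 in ruvAB+ (exact permutation p = 0.0556), more than the lacZ index of ruvAB+. By method, the latter was -0.083 ± 0.011 with phenol-chloroform, -0.022 ± 0.0067 in fixed and -0.0017 ± 0.022 in sonicated libraries (SE, 2 against 2). The deletion without the break changed the mirror index by -0.028 (exact permutation p = 0.037). Without the phenol-chloroform ruvAB+ pair without the break, these 2 ruvAB+ and deletion means, then of fixed and sonicated libraries only, were -0.012 (exact permutation p = 0.333) and -0.0079 (exact permutation p = 0.222). The first passed without sonicated library B of ruvAB+ with the break (-0.042). The second did not pass with narrower windows (-0.015) or 5 kb bins (-0.024), nor without fixed A (-0.027) or B (-0.029) or sonicated B (-0.025) of ruvAB+, or fixed A (-0.025) or sonicated B (-0.026) of the deletion.

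**Figure D2:**
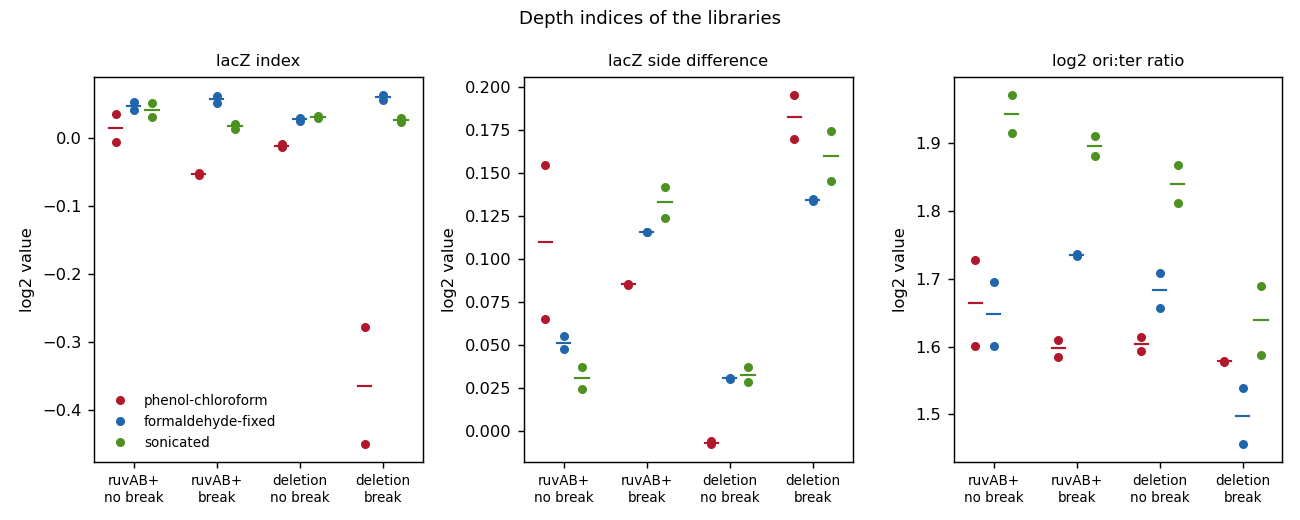
Per-library values of the lacZ index, the lacZ side difference and the log2 ori:ter ratio (log2 units) in the 4 strains, coloured by method. Points are single libraries and bars are means of 2. The phenol-chloroform libraries of the deletion with the break lie at -0.28 and -0.45 on the lacZ index.

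Away from lacZ, depth at the origin relative to the terminus was lower with the break in the ruvAB deletion. Its log2 ori:ter ratio changed by -0.14 with the break (a ratio of 0.909), which had the smallest possible exact permutation p, 0.00926. This ratio compares the windows at the origin and the terminus and does not measure the slope between them. The change was -0.20 ± 0.058 in sonicated, -0.19 ± 0.049 in fixed and -0.026 ± 0.010 in phenol-chloroform libraries (SE, 2 against 2). The spread of 0.18 over methods was not past the threshold (exact permutation p = 0.420). In ruvAB+ the ratio changed by -0.0089 (exact permutation p = 0.796), with methods going both ways: -0.066 ± 0.064 with phenol-chloroform, 0.087 ± 0.047 in fixed and -0.047 ± 0.032 in sonicated libraries. The difference between genotypes was -0.13 (exact permutation p = 0.0489), from 0.041 ± 0.065 with phenol-chloroform, -0.27 ± 0.068 in fixed and -0.15 ± 0.066 in sonicated libraries. It did not pass with narrower or wider windows, medians, 5 kb bins or a pseudocount of 0.1 (-0.13 to -0.11, exact permutation p = 0.0571 to 0.0777). With 1 library left out it passed in 7 of 24 cases (-0.15 to -0.11), and it was furthest from passing without phenol-chloroform library A of ruvAB+ without the break (-0.11, exact permutation p = 0.125). Without the break, the deletion itself changed the ratio by -0.043 (exact permutation p = 0.250).

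Relative to the library mean, higher depth was called around the terminus. In 10 kb bins, limma found continuous regions of higher depth from 2050 kb in the deletion with the break. With sonication the first of these ran to 2510 kb with a mean log2 of 0.13, and in fixed libraries it ran to 2170 kb with a mean of 0.12. Within these methods, 21.1% and 11.4% of 10 kb bins were higher, but 0 of the 1 kb bins (limma, with 1 bin lower in each method, and 788 and 685 bins in either direction at an unadjusted p under 0.05). With phenol-chloroform the first such region started only at 2680 kb. Averaged over methods, regions of higher depth lay between 2050 and 3350 kb and a region of lower depth from 1050 to 1430 kb (mean -0.12). Over the whole chromosome 731 bins (15.8%) were called, 10.1% higher and 5.66% lower, and 7.84% were called with the replication gradient removed. With depth scaled to the terminus window, 67.1% were called, all lower, and 0% higher, so these directions are relative to the library mean. The terminus index, which compares the terminus with its near flanks, was 0.028 higher with the break in the deletion (exact permutation p = 0.0463), and -0.011 in ruvAB+ (exact permutation p = 0.398, but -0.021 and p = 0.0278 without sonicated library B of ruvAB+ without the break). The first of these no longer passed in 5 kb bins (p = 0.0556, exact permutation) or with a pseudocount of 0.1 (p = 0.0648, exact permutation). Nor did it pass without phenol-chloroform library A (0.027) or B (0.028), fixed B (0.023) or sonicated A (0.020) with the break, or without phenol-chloroform B (0.021), fixed A (0.029) or B (0.027) or sonicated A (0.031) or B (0.024) without it.

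**Figure D3:**
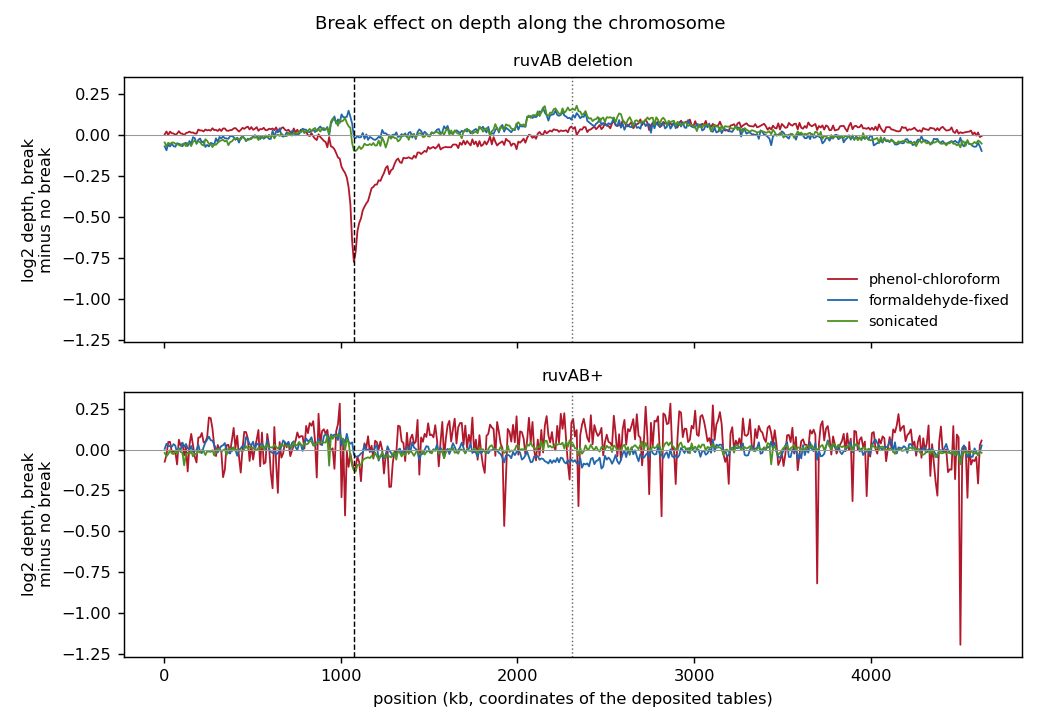
Log2 depth with the break minus log2 depth without it along the chromosome, in medians of 10 kb, for the ruvAB deletion (top) and ruvAB+ (bottom), with the break site (dashed) and the terminus estimate (dotted, 2309 kb). Lines are means of 2 libraries against 2 for each method. In the deletion, sonicated and fixed lines are raised from 2050 kb relative to each library's mean depth, whereas with scaling to the terminus window 0% of bins averaged over methods were higher.

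With RuvAB present, depth differences with the break near lacZ were small in fixed and sonicated DNA. Whether they were smaller than in the deletion depended on place and scaling. In the deletion, log2 differences at 5 to 25 kb on the terminus side were -0.092 with sonication and -0.012 in fixed libraries. Scaled to the terminus window they were -0.25 and -0.13. At 25 to 50 kb on the origin side the deletion had 0.078 and 0.12, and ruvAB+ 0.043 and 0.063. In ruvAB+, depth with the break at 5 to 25 kb on the terminus side was 0.923 times that without it with sonication (-0.12 ± 0.0099, SE, 2 against 2, and -0.14 when scaled to the terminus window). In fixed libraries it was 0.976 times (-0.035 ± 0.0093, but 0.045 when scaled to the terminus window). On the origin side, the log2 difference at 5 to 25 kb was -0.055 ± 0.013 with sonication and 0.051 ± 0.016 in fixed libraries. At 50 to 100 kb depth was higher by 4.86% and 4.58% (0.068 ± 0.016 and 0.065 ± 0.0036), or 0.046 and 0.15 on the log2 scale when scaled to the terminus window. By method, the lacZ index changed by -0.067 ± 0.021 with phenol-chloroform, 0.0095 ± 0.0080 in fixed and -0.025 ± 0.011 in sonicated libraries (SE, 2 against 2). The phenol-chloroform value rests on a pair without the break whose local profile differed from the other phenol-chloroform libraries. The average change of the index was -0.028 (exact permutation p = 0.0833). It passed with narrower windows (-0.066, exact permutation p = 0.0185) and without fixed library B of ruvAB+ without the break (-0.030, exact permutation p = 0.0463). In the 1 kb bins, limma called 2 in fixed and 2 in sonicated libraries, both within a segment near 1068 kb described among the other observations, and 465 and 155 at an unadjusted p under 0.05.

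The averaged bin counts that involve ruvAB+ without the break rested on 1 pair of libraries. Averaged over methods, the break effect in ruvAB+ had 2129 called bins (46.0%, 26.6% higher and 19.4% lower), and the ruvAB deletion without the break had 1889 (40.8%). Both come from the phenol-chloroform libraries, where 65.7% and 63.4% of bins were called, spread over the whole chromosome. The phenol-chloroform ruvAB+ pair without the break differed from every other phenol-chloroform library in its local profile and in noise (0.21 against 0.28 to 0.29 in the other 3 groups). Without this pair, 0.173% and 0.0432% of bins were called. As the pair is its whole group, leaving it out also removes phenol-chloroform from these averages, which are then of fixed and sonicated libraries only. In fixed and in sonicated libraries, the deletion without the break was called in 2 bins each, which hold the ruvAB gap (log2 -5.63 and -1.19 in fixed, -5.62 and -1.35 in sonicated libraries), and in 217 and 227 bins at an unadjusted p under 0.05. With scaling to the terminus window 23.0% of bins were called for the deletion without the break.

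The break effect differed between the genotypes in 1592 bins (34.4%, 18.0% higher and 16.3% lower in the deletion). Without that pair, where here and below only fixed and sonicated libraries could be compared, it differed in 4.84%. In 10 kb bins the region from 1060 to 1230 kb was lower in the deletion than in ruvAB+ (mean -0.13), and regions between 2090 and 2600 kb were higher, with means of 0.083 to 0.11. A region from 4140 to 4190 kb, far from the break, was lower (mean -0.064). All these regions come from the fit that includes that pair. With scaling to the terminus window 62.2% were called, 57.5% lower and 4.71% higher. For the lacZ index the difference was -0.081 (exact permutation p = 0.330). It came from -0.28 ± 0.089 with phenol-chloroform, against 0.023 ± 0.0091 in fixed and 0.020 ± 0.012 in sonicated libraries (SE). The terminus index of the deletion without the break was -0.033 relative to ruvAB+ (exact permutation p = 0.0463), and -0.020 without that pair (exact permutation p = 0.278). It did not pass either without phenol-chloroform library A (-0.030) or B (-0.036), fixed B (-0.029) or sonicated A (-0.023) of ruvAB+, or without phenol-chloroform A (-0.040) or B (-0.027), fixed A (-0.034) or B (-0.033) or sonicated A (-0.037) or B (-0.030) of the deletion.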

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

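The tests on the valley, on the library pair and on the nearness of steps to peaks were chosen only after the result was seen. The search for steps in sonicated libraries with its test in fixed libraries, and the counts of other splits, were set down before their result was seen.

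Around the break in the ruvAB deletion, phenol-chloroform libraries had a valley that the other methods did not show at this depth. The break effect differed between methods in 6.13% of bins for phenol-chloroform against sonicated and in 7.17% against fixed libraries. Of the bins within 100 kb of the break, 88.5% were lower with phenol-chloroform than with both other methods, so the fall measured was not equal across methods. This share restates the valley that prompted it, and its neighbouring bins come from the same 2 libraries with the break (lacZ indices -0.28 and -0.45). The labels do not say whether the methods shared cultures, so a loss of copies that was larger in the phenol-chloroform cultures stays open. A standing bias of these libraries at lacZ is argued against by the index of -0.011 without the break. Scaled to the terminus window, the share of bins lower than with both other methods was 35.5%. The mean difference then shrank and its SE rose, from -0.39 ± 0.093 to -0.27 ± 0.11 against sonicated and from -0.44 ± 0.093 to -0.36 ± 0.097 against fixed libraries. Each SE rests on 2 libraries per group and mostly on the spread of the phenol-chloroform libraries, so a multiple of it is no test. The planned exact permutation test of the spread of the lacZ index over methods did not pass (p = 0.187). As sonicated and fixed libraries had -0.16 and -0.075 with terminus scaling, a smaller loss that all methods show stays open. Organic extraction and the tagging kit cannot be told apart, since 0 methods used 1 of them without the other, and a candidate explanation, not tested, is that DNA near an unrepaired break in cells without RuvAB, which may hold branched molecules, is recovered or tagged less well by this method.

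Calls over the whole chromosome in ruvAB+ came with the phenol-chloroform pair of ruvAB+ without the break. An effect of the break that every method would show is argued against, because the phenol-chloroform effect differed from the mean of the other methods in 51.9% of bins. A difference between library batches is consistent with the 0.130% of bins called between phenol-chloroform libraries of ruvAB+ with the break and of the deletion without it, strains that differ in both respects. The variance of the depth difference over positions was 3.10 to 5.80 times the binomial value between this pair and the other phenol-chloroform libraries, and 0.931 to 1.24 times among those others. The labels give no batch, and the design text does not say whether the pair is among the 4 samples taken from an earlier series, so with the pair being its whole group, the break or the genotype within this method cannot be separated from it.

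Depth in the deletion with the break rose in steps in the sonicated libraries. Of these, 5 were ranked in the fixed ones by the share of 401 other places with as large a step. The rank was adjusted over the 5. It compares places along the chromosome and does not measure variation between libraries. The steps at 2196, 1990 and 2563 kb did not pass 0.05 (adjusted rank 0.0622, 0.286 and 0.729). The step at 2053 kb, before the terminus, measured 0.063 ± 0.0043 with sonication and 0.062 ± 0.016 in fixed libraries (SE, 2 libraries against 2). Its adjusted rank was 0.0249. By that rank the step was larger than at most places, since 0.748% of the 401 other places had as large a step. A rise spread over part of the fitted 60 kb would also give a jump. The rank thus cannot tell a sharp step from a gradual rise. In ruvAB+ the step was 0.035 and 0.020 at this place, and the difference between genotypes was not tested. The 2053 kb step lay far from the 7 strong peaks of the fixed libraries, as 94.3% of positions lie as near to one, which argues against a strong peak as its source. The 5 lower peaks, the nearest of them from 2808 to 2815 kb, were left out of that count. Neither GC bias nor a biological explanation was tested. The step at 933 kb measured 0.049 ± 0.018 and 0.075 ± 0.055 (adjusted rank 0.0249). Although 0.249% of other places had as large a step in fixed libraries, it is within 2 SE of 0 there. It thus cannot be told apart from a smooth change. It also lies inside 1 of the strong peaks (0.993% of positions lie as near), so the peak is a candidate explanation for it.

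The effect of the break on the log2 ori:ter ratio differed between genotypes by -0.13 (exact permutation p = 0.0489), with phenol-chloroform going the other way (0.041, against -0.27 in fixed and -0.15 in sonicated libraries). It did not pass with narrower or wider windows, medians, 5 kb bins or a pseudocount of 0.1, and with 1 library left out it passed in 7 of 24 cases (-0.11 and exact permutation p = 0.125 without phenol-chloroform library A of ruvAB+ without the break). Its effect on the terminus index differed between genotypes by 0.038 (exact permutation p = 0.0372), and by 0.020 to 0.054 in the single methods. That did not pass with narrower or wider windows, medians or 5 kb bins (0.027 to 0.034, exact permutation p = 0.0517 to 0.198). With 1 library left out it passed in 11 of 24 cases (0.028 and exact permutation p = 0.145 without sonicated library A of ruvAB+ without the break). The effect on the side difference differed over methods by 0.086 in the deletion (exact permutation p = 0.00889) and by 0.13 in ruvAB+ (exact permutation p = 0.000741). Neither passed with narrower or wider windows or medians (exact permutation p = 0.0622 to 0.617 and 0.0889 to 0.199). The ruvAB+ value was 0.082 without phenol-chloroform library B without the break, and did not pass without fixed library A or B (0.13 each) or sonicated library A or B (0.13 and 0.12) of the same strain. The share of bins whose break effect differed between genotypes was 34.4%. It was 4.84% without the phenol-chloroform ruvAB+ pair without the break, which leaves only fixed and sonicated libraries in this comparison.

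For the bin counts, 100 splits of the libraries were drawn for each, within method or, for comparisons of methods, within strain, the real one included. The real split called the most bins for the break effect in the deletion (731, at most 437 in the others). So it did for the difference between genotypes (1592 and 1563) and for the 3 comparisons of methods. Those had 4134 and 3657 for phenol-chloroform against sonicated, 3816 and 3337 for fixed against sonicated, and 3760 and 3052 for phenol-chloroform against fixed. With 100 splits drawn, being the largest does not exclude chance. For the difference between genotypes, 1563 lies close to 1592, and only 40 of the splits kept the phenol-chloroform ruvAB+ pair without the break together. Other splits reached the real count for the break effect in ruvAB+ (5 splits, 2129 and 2288) and for the deletion without the break (9 splits, 1889 and 2409). Every split as large as the real one in those 2 comparisons kept the phenol-chloroform ruvAB+ pair without the break together, and splits that parted it called 0 bins. Splits that parted the pair called at most 71 bins for the difference between genotypes, 25 for phenol-chloroform against sonicated and 2992 for phenol-chloroform against fixed libraries, so the counts of the first 2 also move with whether the pair is kept together.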

How the results depend on the processing

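The settings that leave out the phenol-chloroform ruvAB+ pair without the break, count the phenol-chloroform deletion pair without the break as 1, leave out strain segments, remove the method baseline or rescale the values by distance were chosen after the data were seen, as were the settings for the share of bins near the break lower with phenol-chloroform. Leaving out the ruvAB+ pair removes phenol-chloroform from every comparison with ruvAB+ without the break, so only fixed and sonicated libraries remain in those. For the main results, to which the values by distance and that share do not belong, 195 of 227 values under the settings kept their side of the threshold, and their direction where past it, or stayed within 1.5 times their count. Of 576 values with 1 library left out, 546 did, and 0 called values of either kind were reversed. Both tallies include values that could not change. The filter had removed 0 bins, so the setting without it repeats the main values. An index test within 1 genotype does not use the libraries of the other, so leaving those out changes nothing. Of 60 values by distance, terminus scaling left 9 within 1 SE and moved 41 lower and 10 higher, and median scaling left 49 and moved 9 lower and 2 higher. No paired analysis was possible because the columns carry letters that are not tied to the repeat numbers. The GC correction, the replicate block and their combination were not run, nor were the alternatives for genes and prophages. For the lacZ index, the index simulated, a shift of 0.05 that was equal in all methods passed the threshold in 47.5% of simulations.

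In every result of this part the cause was not tested, except where named. Narrower windows gave -0.066 for the lacZ index in ruvAB+, 0.041 for its side difference and -0.024 for the terminus index of the deletion without the break. Wider windows gave 0.074 for that side difference and -0.022 for that terminus index. The latter was -0.026 with medians, -0.031 in 5 kb bins, -0.020 without the phenol-chloroform ruvAB+ pair and -0.033 with the deletion pair counted as 1, with p no longer under 0.05. The terminus effect of the break in the deletion was 0.026 in 5 kb bins and 0.023 with a pseudocount of 0.1, also past 0.05. The side difference in ruvAB+ was 0.058, past the threshold, without strain segments, and the method spread of the lacZ index in the deletion, 0.39, passed once the baseline was removed.

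For the break effect in the deletion, bins called were 35.9% in 5 kb and 40.5% in 10 kb bins, where averaging lowers noise, 67.1% (all lower, 0% higher) with scaling to the terminus window, 7.84% with the gradient removed and 9.59% with the deletion pair counted as 1. Phenol-chloroform against sonicated gave 17.4%, 29.5%, 1.58% and 3.76% in 5 kb bins, 10 kb bins, terminus scaling and gradient removal. Phenol-chloroform against fixed gave 20.9%, 26.1%, 3.09% and 4.21%, and 11.2% (5.87% higher, 5.36% lower) with median scaling, beside 0.345% higher and 6.82% lower as reported. Terminus scaling moved the median of all bins by -0.10 for the break effect in the deletion, -0.11 for the difference between genotypes, 0.12 for the break effect of phenol-chloroform against sonicated, and -0.24 and -0.26 for phenol-chloroform and fixed against sonicated libraries. It gave 62.2% for the difference between genotypes (57.5% lower) and 23.0% for the deletion without the break (9.41% higher, 13.6% lower). Without the phenol-chloroform ruvAB+ pair without the break, these 2 were 4.84% and 0.0432%, and the break effect in ruvAB+ was 0.173%.

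Leaving out 1 library at a time gave -0.034 to -0.021 for the lacZ index in ruvAB+ (past the threshold without fixed library B of ruvAB+ without the break, -0.030), 0.032 to 0.062 for its side difference (past it without phenol-chloroform library B of ruvAB+ without the break, 0.062), 0.020 to 0.035 for the terminus effect of the break in the deletion and -0.043 to -0.023 for the terminus index of the deletion without the break. The break effect in the deletion was called in 8.44% to 19.4% of bins. It was 10.0% without phenol-chloroform library B with the break, 10.0% and 9.91% without phenol-chloroform A and B without it, 8.66% without fixed B with the break, 9.09% without fixed B without it, 9.20% without sonicated A with the break and 8.44% without sonicated B without it. Phenol-chloroform against sonicated ranged from 3.63% to 7.97%, and against fixed from 4.47% to 8.87%, the lowest without phenol-chloroform library B of the deletion with the break.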

Other observations

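The tests of the segment near the break and of the drop at the break were chosen only after the result was seen, while the test of the peaks was set down before its result.

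A segment of 769 bases from 1068415 to 1069183 on the origin side of the break, had more depth than its flanks in strains without the palindrome. The ratio to the flanks was 2.41 ± 0.22 (SD, n = 12) without and 1.27 ± 0.11 (SD, n = 12) with the palindrome, and the lowest library without it (2.11) lay above the highest with it (1.41). At the scale of 1 kb, the bins of this segment made up the calls in fixed and sonicated libraries for the break effect in ruvAB+ (log2 -0.58 and -0.30 in fixed, -0.69 and -0.33 in sonicated libraries) and in the deletion (-0.62 and -0.68). A second segment of 181 bases, from 1074917 to 1075097, surrounds the break site, at 0.467 ± 0.086 of its flanks with and 0.729 ± 0.23 without the palindrome (SD, n = 12 each).

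With strain segments masked, the largest fall within 30 kb of the break in the deletion lay on its origin side, at 1062 kb in sonicated (-0.11 ± 0.011, SE), 1072 kb in fixed (-0.13 ± 0.024) and 1060 kb in phenol-chloroform libraries (-0.31 ± 0.045). In ruvAB+ it lay on that side at 1052 kb in sonicated (-0.098 ± 0.015) and 1068 kb in fixed libraries (-0.086 ± 0.0028), but on the terminus side, at 1085 kb, with phenol-chloroform (-0.19 ± 0.015). These positions are no test of where depth starts to fall.

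Fixed libraries had 7 strong peaks of depth over sonicated ones, starting at 16, 109, 237, 279, 932, 3431 and 4128 kb, each 5 or 6 kb long and 2.06 to 2.38-fold, and 5 other, lower ones. Relative to their flanks the strong peaks averaged 1.04 ± 0.096 on the log2 scale in fixed, 0.31 ± 0.036 in phenol-chloroform and -0.22 ± 0.19 in sonicated libraries (SD, n = 8 each). A hypothesis is that they are copies of 1 repeated sequence, such as the ribosomal RNA operons, among which the aligner spread reads evenly, so that peak depth may not follow the depth of the flanks. The slope of peak on flank depth over the 7 was 0.17 on average and at most 0.194 in the 8 sonicated libraries, as that needs, against 0.82 for the 5 other peaks. With phenol-chloroform the classes were closer, at 0.251 and 0.471, the other peaks ranging from 0.343 to 0.871 over its 8 libraries. No gene position was used, so the identity of the sequence was not tested. Even spreading of reads bears on the slope only. It does not account for the difference between methods that defines these peaks, whose cause was not tested.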
